A study of Homo sapiens with 4 samples.

How the data were processed

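Nascent RNA was measured in an established human cell line from an ALK-positive anaplastic large cell lymphoma, a T cell lymphoma that carries the receptor CD30 on its surface. The assay was Bru-seq, in which cells take up bromouridine for a short time and the labelled RNA is captured with an antibody, so that the reads come from RNA made during the labelling window. Per the labels' protocols, cells were treated for 3 h and labelled during the last 30 min. The 4 libraries form 2 experiments. In the first, cells received the solvent DMSO or SM-164, a bivalent Smac mimetic that antagonises the inhibitor of apoptosis (IAP) proteins. In the second, cells were placed on a layer of Chinese hamster ovary (CHO) cells or on CHO cells that carry CD30L, the ligand of CD30, and were then collected by pipetting. The dose of SM-164 is not given in the sources used here. Each condition has 1 library.

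Per the submitters' processing notes, CASAVA 1.8.2, Bowtie 0.12.8, TopHat 1.4.1 and bedtools 2.16.2 were used with genome build hg19. The gene annotation is not given in the sources used here. Each deposited file lists the same 44807 features. Of these, 22984 are genes counted on their own strand, and 48 pool stretches shared by several genes; the others are genes counted on the opposite strand. The authors deposited an estimated read count per feature over exons and introns together. Between 60.6% and 70.8% of the non-zero estimated counts per library lay within 0.001 of a whole number, and the others were fractional. The authors deposited a second column with the signal per base, which equals the estimated count divided by the bases counted for that feature. The authors deposited the RPKM in the last column, scaled by 1 library total per file. Those totals, recovered from the deposited signal and RPKM columns, were 31030478 reads for DMSO, 26217590 for SM-164, 45885631 for CHO and 45535365 for CD30L+ CHO. Sense features held 78.4% to 79.6% of these totals, antisense features 3.31% to 3.57% and pooled stretches 1.57% to 1.75%. The remaining 15.2% to 16.4% lay outside the listed features. Reads from exons and introns cannot be told apart in these values. Counts of near-identical copies, such as histone genes, ribosomal protein genes with processed pseudogenes and HSPA6, are uncertain because shared reads may be split or lost. Unique bases can also be few: TMEM183A was counted over a small part of its length.

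The comparisons used sense features only, as the deposited RPKM. A symbol with several entries kept the one with most counted bases, which left 22798 genes and dropped 186 entries. The log2 ratio was log2((treated RPKM + 0.25)/(control RPKM + 0.25)), a scale that understates differences of low genes. A gene was tested when it had at least 300 counted bases and a mean RPKM of at least 0.5 over the 2 libraries compared, and it was called different at 2-fold or more on this scale. With 1 library per condition there was no replicate test, and no p-value was computed. Folds in the text are ratios of estimated counts, rounded to whole reads and divided by the library totals, without a pseudocount. Each has an exact conditional (Clopper-Pearson) 95% interval, which covers counting error only, since PCR reads without molecular identifiers are not independent molecules. A count of 0 allows up to 3 reads, which is an RPM (the RPKM scale without gene length) of 0.0654 to 0.114 in these libraries.

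The comparisons were SM-164 against DMSO and CD30L+ CHO against CHO, the overlap of both, and CHO against DMSO as a yardstick of how far libraries of the 2 experiments lie apart. For 25 gene lists with 524 distinct members, all of which had an entry, the median log2 ratio was set beside 10000 random lists of the same size matched on mean expression in 10 bins. Its percentile describes these libraries and is no test of the conditions. These lists, the settings above and the rule for named genes were fixed before the data were examined. That rule took, per main comparison, the 15 highest and 10 lowest log2 ratios, at most 4 list members at 2-fold or more per list, and 11 genes of the CD30, IAP and NF-kB pathways whatever their values. For the overlap it took the 10 genes with the highest smaller ratio. Genes outside this rule are marked as chosen after their values were seen.

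The alternatives tried were a pseudocount of 0.1 or 1, no expression minimum or a mean RPKM of at least 1, a minimum of 1000 counted bases, a 1.5-fold threshold, the 2-fold rule with a counting interval that excludes 1, a median log2 ratio set to 0, and TMM scaling of the rounded counts with edgeR 4.0.16 in R 4.3.3. After seeing the data, 2 more were added: subtraction of the running median of the log2 ratio over 301 genes ordered by counted bases, and random lists matched on counted bases. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

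The procedure was tested on simulated data in which counts were drawn for all genes from the control library and 200 genes were given known folds. For SM-164 against DMSO, with 7972 genes tested, 50 of 50 genes raised 3-fold and 40 of 43 lowered 3-fold were called, 0 of 50 raised and 0 of 47 lowered 1.5-fold, and 0 of 7782 without a difference. For CD30L+ CHO against CHO, with 7997 genes tested, 49 of 50 raised 3-fold and 40 of 41 lowered 3-fold were called, 0 of 50 raised and 0 of 47 lowered 1.5-fold, and 1 of 7809 without. Genes given a fold that then fell below the expression minimum, all of them lowered ones, are left out of these counts. The simulation holds counting error alone, not the variation between cultures. No reference genome was used, so GC content was not examined.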

Results

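Nascent RNA of a human anaplastic large cell lymphoma line was profiled by Bru-seq in 4 libraries, 1 per condition: DMSO, SM-164, co-culture with CHO cells, and co-culture with CD30L+ CHO cells. The design sets a synthetic IAP antagonist, SM-164, beside a physiological stimulus, the ligand of CD30. The authors' library totals were 31030478 reads for DMSO, 26217590 for SM-164, 45885631 for CHO and 45535365 for CD30L+ CHO. Expressed genes, at an RPKM of at least 0.5, numbered 7977, 7771, 8009 and 7258 in the same order. No condition was repeated, so no difference below has a replicate check, and the intervals given cover counting error only.

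The first comparison asked which genes were transcribed more or less after 3 h with SM-164. BIRC3, which encodes the IAP protein c-IAP2, stood highest: its RPKM was 40.7 with SM-164 and 6.29 with DMSO, a 6.48-fold difference (95% interval 6.27 to 6.70). Feedback inhibitors of NF-kB were also among the higher genes, with NFKBIA, which encodes the inhibitor IkB-alpha, 2.93-fold higher (2.61 to 3.28) and TNFAIP3, which encodes the ubiquitin-editing enzyme A20, 2.58-fold higher (2.47 to 2.69). TRAF1, an adaptor that binds c-IAP proteins, was 3.06-fold higher (2.88 to 3.25), and RELB, the transcription factor subunit of the non-canonical NF-kB pathway, was 2.79-fold higher (2.54 to 3.06). The response was narrow: of 7881 genes tested, 15 were at least 2-fold higher and 5 at least 2-fold lower.

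The other 10 genes on the higher side were HMSD, RGS1, ZC3H12D, GPR132, PTGER4, NFKBIE, SERPINB8, IL21R, MSC and JMY, with log2 ratios from 1.58 for HMSD down to 1.00 for JMY. RGS1, a regulator of G protein signalling in lymphocytes, reached an RPKM of 11.9 against 4.12, and PTGER4, a prostaglandin E2 receptor, 9.07 against 3.66. IL21R, the interleukin 21 receptor, was at 5.10 against 2.19. NFKBIE, another IkB protein, was at 1.54 against 0.528.

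In hg19 coordinates, BIRC3 lies on chromosome 11 from 102188181 to 102210135, with BIRC2 downstream on the same strand from 102217966 to 102249401. NFKBIA lies on chromosome 14 from 35870716 to 35873960, and TNFAIP3 on chromosome 6 from 138188581 to 138204449. TRAF1 lies on chromosome 9 from 123664671 to 123691451, and RELB on chromosome 19 from 45504707 to 45541456. All values count exons and introns of a gene together.

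BIRC3 encodes a direct target of SM-164, and the other IAP and CD30 pathway genes of this comparison differed less than it did. BIRC2, which encodes c-IAP1, was 1.20-fold higher (1.14 to 1.27), and XIAP 1.07-fold higher (1.01 to 1.13). MAP3K14, which encodes the NF-kB inducing kinase NIK, was 1.07-fold higher (1.02 to 1.11). TNFRSF8, which encodes CD30, was 1.29-fold higher (1.26 to 1.31), and NFKB2, the precursor of p52, 1.35-fold higher (1.14 to 1.62). TNFSF8, which encodes CD30L, had 0 reads with SM-164 and 1 read with DMSO, so a difference was not detectable at this depth.

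Among the fixed gene lists, NF-kB subunits and feedback inhibitors had the highest median log2 ratio, 0.52 over 15 tested members. Of these, 4 were at least 2-fold higher, 0 were lower and 11 differed less. NF-kB targets in survival, adhesion and costimulation had a median of 0.31, with BIRC3 and TRAF1 the 2 of 14 tested members at 2-fold or more. Both medians exceeded all 10000 matched lists. The same held for the TNF receptor superfamily (median 0.24, 7 tested) and for JAK-STAT and SOCS genes (0.14, 17 tested), where IL21R was the 1 member above 2-fold. Medians of 0.29 for TNF superfamily ligands (3 tested, percentile 99.4), 0.12 for T cell identity and signalling (6 tested, 99.0) and 0.10 for immediate-early and AP-1 genes (18 tested, 99.97) came without a member at 2-fold.

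Smaller positive medians were found for cytokines and chemokines (0.10, 5 tested, percentile 97.3), for the IAP family and IAP antagonists (0.08, 9 tested, 98.8), for the c-IAP complex and NF-kB upstream regulators (0.05, 20 tested, 99.6) and for the anaplastic large cell lymphoma program (0.05, 14 tested, 98.9). BIRC3 was the 1 IAP family member at 2-fold. The median of the c-IAP complex list was higher between the controls, as given below. Caspases, BCL2 family and necroptosis genes (-0.02, 14 tested, percentile 74.8), p53 targets (-0.04, 14 tested, 47.8), the interferon response (-0.09, 9 tested, 31.2), hypoxia and glycolysis (-0.06, 11 tested, 54.7), S and G2/M phase genes (-0.10, 28 tested, 24.2) and MYC and ribosome biogenesis genes (-0.10, 13 tested, 19.8) lay within the range of the matched lists. The medians of caspases and p53 targets turned positive with the median of all genes set to 0, that of caspases also under TMM scaling, and both, with the interferon and MYC lists, did so with the length trend subtracted.

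Ribosomal proteins had the lowest median, -0.38 over 30 tested members, below all 10000 matched lists, with 0 members at 2-fold. It was -0.22 with the length trend subtracted. Heat shock genes (-0.35, 11 tested, percentile 0.09), cholesterol synthesis (-0.24, 15 tested, 0.2), cytoskeleton and serum response (-0.19, 9 tested, 5.14) and the unfolded protein and amino acid response (-0.18, 18 tested, 1.04) were also below 0. Against lists matched on gene length, the last of these lay at percentile 4.33. Of the cell type controls, the stromal list had 3 tested members (-0.17, percentile 9.52), the list of B cell, myeloid and NK cell markers 3 (0.03, 80.6) and the epithelial list 0.

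The 5 genes at least 2-fold lower with SM-164 were the replication-dependent histone genes HIST1H4D, HIST1H4I and HIST1H2AI, with log2 ratios of -1.16, -1.13 and -1.10, together with TMEM183A (-1.09) and C1orf122 (-1.08). The next 5 were IER5L (-0.99), HIST1H2BL (-0.98), HIST1H3F (-0.98), IRF2BP1 (-0.95) and HIST1H2AH (-0.95). Over all 57 tested histone genes with HIST symbols, a group picked after their values were seen, the median was -0.68. All 5 lower genes lay in the shortest decile of counted bases, at most 3390 bases, where the median log2 ratio of all genes was -0.27 against 0.03 in the longest decile. The 15 higher genes were reduced to 8 with a pseudocount of 1, and the 5 lower genes to 1 with a minimum of 1000 counted bases and to 0 once the length trend was subtracted. After that subtraction the ratios of these 5 genes were still between -0.82 (HIST1H4D) and -0.75 (TMEM183A). Because they were chosen as 2-fold lower on the same ratios, values well below 0 were bound to remain.

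The second comparison asked what CD30 engagement by its ligand did beyond contact with CHO cells. BIRC3 again stood highest, with an RPKM of 54.8 on CD30L+ CHO cells and 5.37 on CHO cells, a 10.2-fold difference (9.93 to 10.5). IL8, which encodes the neutrophil chemokine CXCL8, was 9.97-fold higher (7.60 to 13.3). TNFAIP3 was 6.29-fold (6.11 to 6.47), NFKBIA 6.08-fold (5.68 to 6.52), TRAF1 5.99-fold (5.80 to 6.20) and RGS1 6.48-fold higher (6.15 to 6.83). The adhesion molecule gene ICAM1 was 5.08-fold higher (4.80 to 5.37) and NFKBIZ, an atypical nuclear IkB gene, 5.21-fold higher (4.93 to 5.51). Of 7661 genes tested, 75 were at least 2-fold higher and 56 at least 2-fold lower.

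The remaining genes among the 15 highest were HMSD (log2 ratio 2.45), PTGER4 (2.24), SERPINB8 (1.94), TNF (1.89), BATF (1.88), FAS (1.88) and DRAM1 (1.83). TNF, the cytokine tumour necrosis factor, was 5.49-fold higher (4.01 to 7.66) from a low level of 46.5 estimated reads on CHO cells. FAS, a death receptor, was 4.28-fold higher (4.03 to 4.55), and BATF, an AP-1 family transcription factor of lymphoid cells, 4.01-fold higher (3.83 to 4.20).

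IL8 lies on chromosome 4 from 74606223 to 74609433, ICAM1 on chromosome 19 from 10381517 to 10397291 and NFKBIZ on chromosome 3 from 101547076 to 101579869 (hg19). TNF lies on chromosome 6 from 31543350 to 31546112, FAS on chromosome 10 from 90750288 to 90775542 and BATF on chromosome 14 from 75988784 to 76013334. MYC, named below, lies on chromosome 8 from 128748315 to 128753680.

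Both c-IAP genes were higher on CD30L+ CHO cells: BIRC2 was 2.63-fold higher (2.55 to 2.72), with an RPKM of 9.27 against 3.52. XIAP was 1.16-fold higher (1.11 to 1.21). RELB was 3.41-fold (3.21 to 3.63) and NFKB2 2.59-fold higher (2.21 to 3.04). MAP3K14 was at 0.845 of its level on CHO cells (0.814 to 0.878), a log2 ratio of -0.22. The median of all tested genes was -0.12, and TMM scaling moved it by 0.17. The MAP3K14 difference therefore depends on scaling, which the counting interval leaves out. TNFRSF8 was 1.03-fold higher (1.01 to 1.05), a log2 ratio of 0.04, which is smaller than these effects of scaling. TNFSF8 had 100 reads on CD30L+ CHO cells and 1 read on CHO cells, a ratio of 101 with a counting interval from 17.7 to 4019, at an RPKM of 0.0590, below the expression minimum.

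**Figure D1:**
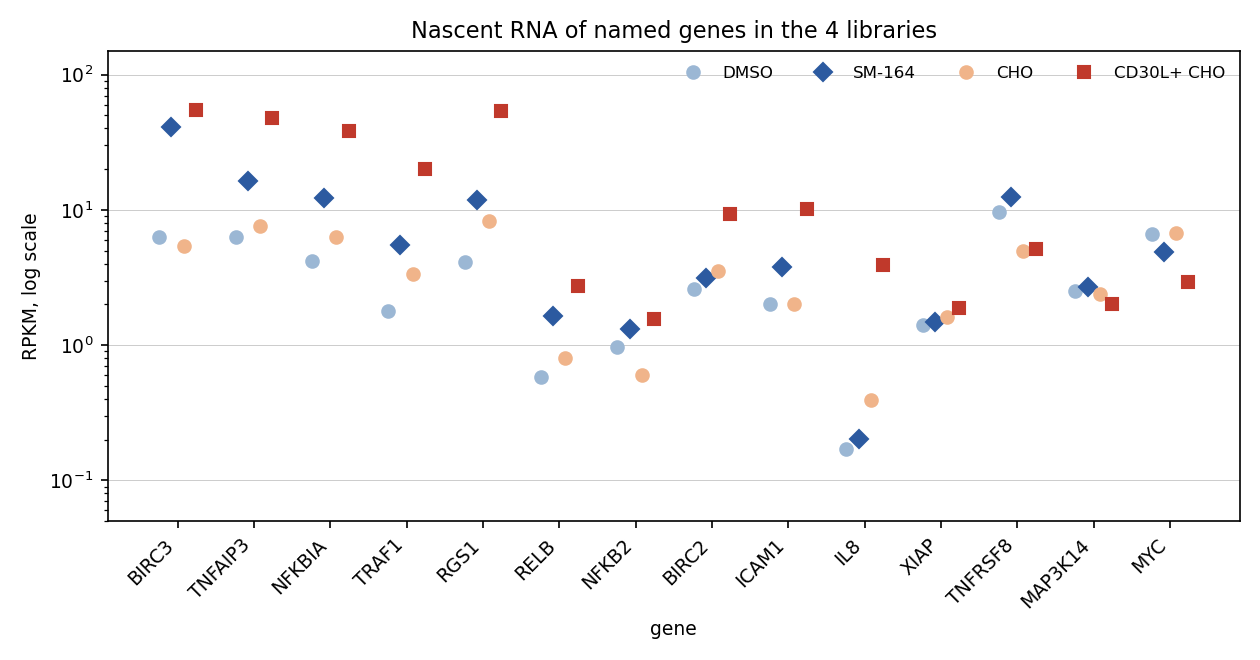
RPKM of 14 genes (log scale) in the DMSO, SM-164, CHO and CD30L+ CHO libraries, 1 point per library. BIRC3 stands at 6.29, 40.7, 5.37 and 54.8, while MAP3K14 lies between 2.02 and 2.68.

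NF-kB subunits and feedback inhibitors had a median log2 ratio of 1.07, and 9 of 15 tested members were at least 2-fold higher, led by TNFAIP3, NFKBIA, NFKBIZ and RELB. NF-kB targets in survival, adhesion and costimulation had a median of 0.78, with 6 of 15 at 2-fold or more, among them BIRC3, TRAF1, ICAM1 and the superoxide dismutase gene SOD2 (log2 ratio 1.82). TNF superfamily ligands had a median of 0.78 over 5 tested members, with TNF and TNFSF10, the gene of the death ligand TRAIL (1.61), above 2-fold. TNF passed the expression minimum only through its value on CD30L+ CHO cells, an RPKM of 2.03 against 0.367. The median of so short a list leans on that choice. JAK-STAT and SOCS genes had a median of 0.34 over 18, with the signalling suppressor SOCS2 (1.03) above 2-fold. Each of these 4 medians exceeded all 10000 matched lists.

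Immediate-early and AP-1 genes had a median of 0.15 over 21 tested members (percentile 99.99), with BATF, BATF3 (1.38) and the antiproliferative gene BTG2 (1.37) above 2-fold and MYC (-1.14) among 2 lower. Cytokines and chemokines had a median of 0.34 over 5 (98.2), with IL8 and IL22 (1.29) above 2-fold. IL8 passed the expression minimum only through its value on CD30L+ CHO cells, an RPKM of 3.93 against 0.394. IL22, a cytokine of T helper cells, was already at an RPKM of 20.8 on CHO cells and reached 51.1. The IAP family and IAP antagonists had a median of 0.18 over 9 (99.7), with BIRC3 and BIRC2 above 2-fold. The c-IAP complex and NF-kB upstream regulators had a median of 0.04 over 20 (99.6), with TANK (1.39), an adaptor of TRAF proteins and the kinase TBK1, and BIRC2 above 2-fold. The median of this list was higher between the controls, as given below. The TNF receptor superfamily had a median of 0.04 over 7 (95.3), with FAS above 2-fold. For p53 targets the median was 0.03 over 14 (98.3), with FAS, BTG2 and GADD45A (1.09) higher and the kinase gene PLK3 (-1.07) lower.

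The interferon response had a median of -0.16 over 11 tested members (percentile 35.6), 0.04 with the length trend subtracted, and the guanylate-binding protein genes GBP4 (1.21) and GBP1 (1.09) were above 2-fold. In the anaplastic large cell lymphoma program (median -0.09, 14 tested, 20.1), BATF, BATF3 and SERPINA1 (1.15) were higher and MYC was among 2 lower. T cell identity and signalling genes had a median of -0.40 over 5 (2.29), with CD274, the gene of the immune checkpoint ligand PD-L1 (1.49), higher and the T cell receptor kinase gene ZAP70 (-1.36) lower. CD274 was 2.88-fold higher (2.80 to 2.97). ZAP70 was at 0.224 of its control level (0.138 to 0.351), from 23.9 estimated reads against 108. Only 2543 of its 26293 bases were counted, and it belongs to the mostly short lower genes weighed below.

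MYC and ribosome biogenesis genes had the lowest median, -0.48 over 12 tested members, and ribosomal proteins had -0.42 over 30. Both lay below all 10000 matched lists. Both lists were also low between the controls, where no CD30L was present, as given below. MYC itself, the proto-oncogene that drives growth and ribosome production, was at 0.433 of its control level (0.396 to 0.473). RPL35 (-1.33), RPS15 (-1.25) and RPLP1 (-1.06) were the 3 ribosomal protein list members lower by 2-fold. Medians were -0.35 for cytoskeleton and serum response (9 tested, percentile 0.31), -0.29 for caspases, BCL2 family and necroptosis (15 tested, 0.93) and -0.26 for hypoxia and glycolysis (12 tested, 0.84), without a member at 2-fold. These negative medians were nearer 0 under TMM scaling: -0.30 for the MYC list, -0.22 for ribosomal proteins, -0.14 for cytoskeleton, -0.12 for caspases and -0.08 for hypoxia. The T cell median was -0.21 under this scaling. Small positive medians rose, to 0.24 for the c-IAP complex, 0.22 for the TNF receptor superfamily and 0.19 for p53 targets. With the length trend subtracted, the median of ribosomal proteins was -0.18.

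Heat shock genes (-0.17, 12 tested, percentile 5.45), S and G2/M phase genes (-0.16, 27 tested, 3.49), cholesterol synthesis (-0.13, 16 tested, 17.1), the B cell, myeloid and NK cell markers (-0.13, 3 tested, 66.0) and the unfolded protein and amino acid response (-0.02, 17 tested, 66.8) had medians that turned positive under TMM scaling. So did the lymphoma program, which turned positive with the median of all genes set to 0 too, like the unfolded protein list. With the length trend subtracted, the heat shock and unfolded protein medians were positive. Against lists matched on gene length, an alternative chosen after seeing the data, the percentiles were 43.1 for heat shock, 37.0 for S and G2/M phase, 49.9 for cholesterol synthesis, 98.3 for the unfolded protein response and 81.0 for the lymphoma program. Outside the lymphoma program, the members of these lists at 2-fold were the small heat shock protein gene HSPB1 (-1.80) and the cytotoxic granule gene NKG7 (-1.08). The stromal list had 1 tested member and the epithelial list 0.

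**Figure D2:**
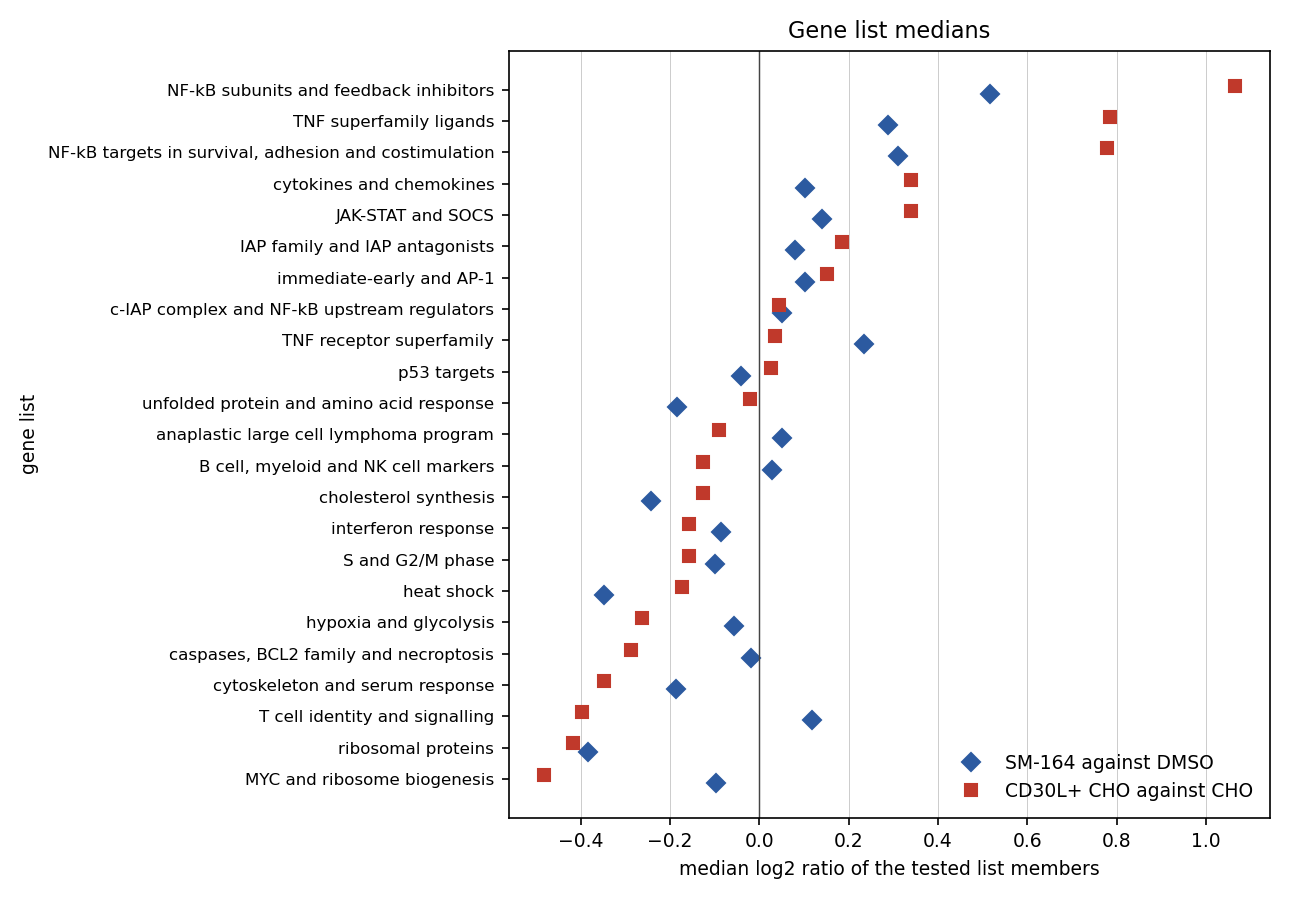
Median log2 ratio of the tested members of each gene list with at least 3 tested members in both comparisons, for SM-164 against DMSO (diamonds) and CD30L+ CHO against CHO (squares). NF-kB subunits and feedback inhibitors lead both, at 0.52 and 1.07, and ribosomal proteins lie at -0.38 and -0.42.

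The 10 lowest ratios on CD30L+ CHO cells belonged to SCARNA2 (-2.40), RPS28 (-2.22), HIST1H4L (-2.16), HSPB1 (-1.80), HIST1H2AH (-1.78), RPL36 (-1.74), IFITM3 (-1.66), SCARNA17 (-1.66), CRIP1 (-1.63) and HIST1H1B (-1.51). They are small Cajal body RNA, histone, ribosomal protein and other short genes, and several rest on few reads: SCARNA2 had 1 read against 26, a ratio of 0.0388 with a counting interval from 0.000945 to 0.236. Of the 56 lower genes, 42 lay in the shortest decile of counted bases, at most 3961 bases, where the median log2 ratio of all genes was -0.27. Histone genes with HIST symbols made up 13 of the 56, and their share of all reads was 0.00464% on CD30L+ CHO cells, 0.00825% on CHO cells, 0.0557% with SM-164 and 0.0917% with DMSO.

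The median log2 ratio of all tested genes was -0.12 in this comparison, and TMM scaling moved it by 0.17. The split of 75 higher to 56 lower genes became 113 to 32 with TMM scaling and 92 to 40 with the median set to 0; the lower count was 24 once the length trend was subtracted, and 15 with a pseudocount of 1.

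The third question was how far the responses to the synthetic and the physiological stimulus overlapped. Of 7210 genes tested in both comparisons, 14 were at least 2-fold higher in both, against 15 with SM-164 and 68 with CD30L+ CHO cells. Independent lists of these sizes would share 0.141 genes. The 10 with the highest smaller ratio were BIRC3, HMSD, NFKBIA, TRAF1, RGS1, ZC3H12D, GPR132, TNFAIP3, PTGER4 and SERPINB8. The SM-164 gene that did not reach 2-fold on CD30L+ CHO cells was IL21R, whose log2 ratio there was 0.84 against 1.13. This call depends on scaling: under TMM, 17 genes were higher with SM-164 and all 17 were higher in both. A single gene, the histone gene HIST1H4D, was 2-fold lower in both (-1.16 and -1.04), and 0 genes were 2-fold different in opposite directions. Of the 56 genes lower on CD30L+ CHO cells, 52 were below 0 with SM-164 as well, with a median of -0.40 there against -1.21 with CD30L. Most of these genes are short, and the shortest decile of all genes had a median of -0.27 and an upper quartile of -0.06 with SM-164, so a count below 0 sets them little apart.

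Among the 68 genes higher on CD30L+ CHO cells and tested with SM-164, 64 had a log2 ratio above 0 with SM-164 and 40 reached 1.5-fold. Their median log2 ratio was 1.31 with CD30L and 0.70 with SM-164, and 67 of 68 had the larger ratio with CD30L. This set was chosen on the CD30L ratios, which favours that order; of the 15 genes chosen on the SM-164 ratios, 13 still had the larger ratio with CD30L. SM-164 ratios within 0.2 of 0 were found for 6 of the 68: SOD2, G0S2, AQP9, SERPINA1, GADD45A and GBP1. SOD2 had an RPKM of 0.889 with SM-164 and 0.896 with DMSO, but 4.16 and 0.999 on CD30L+ CHO and CHO cells. G0S2 and AQP9 were chosen after their values were seen.

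Across the 7210 genes, the log2 ratios of the 2 comparisons had Pearson's r = 0.57 and Spearman's rho = 0.40; genes are not independent replicates, and the comparisons share no library. The shared trend with gene length contributes to this figure, and r was 0.52 with that trend subtracted from both.

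**Figure D3:**
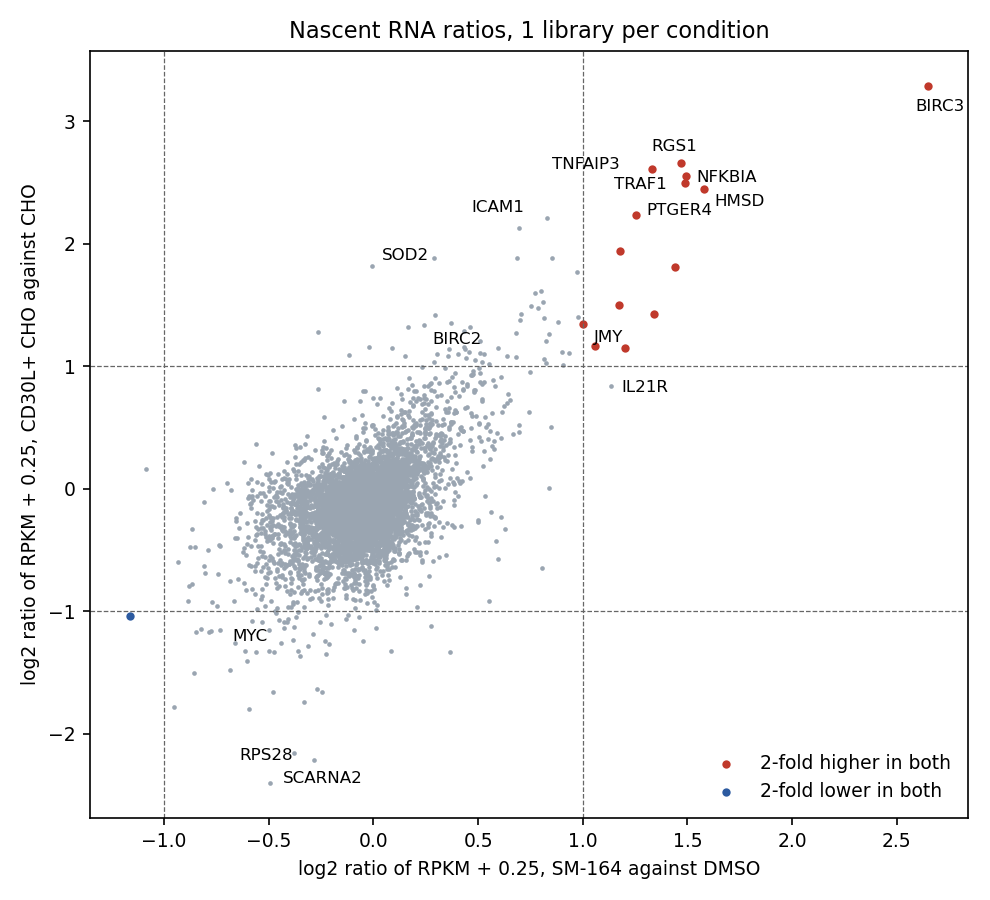
Log2 ratio of each gene tested in both comparisons, with SM-164 against DMSO on the x axis and CD30L+ CHO against CHO on the y axis; dashed lines mark 2-fold. The 14 genes at upper right are 2-fold higher in both, with BIRC3 at 2.65 and 3.29, and SOD2 is at -0.01 and 1.82.

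The controls of the 2 experiments, CHO against DMSO, gave the yardstick for differences without either agent. Of 8081 genes tested, 71 were at least 2-fold higher with CHO cells and 365 at least 2-fold lower, 436 in all, with an SD of log2 ratios across genes of 0.59 against 0.21 for SM-164 and 0.33 for CD30L. With the length trend subtracted the split was 133 higher and 233 lower, and with a pseudocount of 1 it was 18 and 209. Culture and experiment differ together here. NF-kB subunits and feedback inhibitors had a median of 0.33 (percentile 99.5), with 12 of 15 tested members above 0 and 0 at 2-fold, and BIRC3 had an RPKM of 5.37 on CHO cells and 6.29 with DMSO. The c-IAP complex and NF-kB upstream regulators had a median of 0.32 (99.8), with 16 of 20 above 0. That exceeds their medians of 0.05 with SM-164 and 0.04 with CD30L, so those small medians cannot be read as a response to either agent. Cholesterol synthesis had a median of 0.37 (99.97).

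The genes named for this yardstick were chosen after their values were seen. Histone genes with HIST symbols were at least 2-fold lower with CHO cells in 55 of 56 tested cases, with a median log2 ratio of -3.88. The small RNA genes RPPH1 (-4.88) and SCARNA2 (-5.36) were lower too. Ribosomal proteins had a median of -0.91, with 14 of 30 lower by 2-fold, S and G2/M phase genes -0.63 and the anaplastic large cell lymphoma program -0.81, with 5 of 14 lower. Other lists that were low with CD30L were low here too: cytoskeleton and serum response (-0.68, percentile 0.12), T cell identity (-0.53, 0.82) and MYC and ribosome biogenesis (-0.35, 1.12). Caspases (0.01, 43.7) and hypoxia and glycolysis (-0.16, 23.8) lay within the range of the expression-matched lists. Against lists matched on gene length, however, hypoxia and glycolysis lay at percentile 1.78. On the higher side were the inducible heat shock gene HSPA6 (2.51), the thymocyte selection gene THEMIS (2.10), MYO18B (2.04), SLAMF7 (1.73) and the phosphatase gene DUSP1 (1.70). HSPA6 had 151 reads against 1, a ratio of 102 with a counting interval from 18.1 to 4060.

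Stromal genes, as counted on hg19, did not mark the libraries made with CHO cells. How much hamster RNA aligns to hg19 was not examined, so these values cannot show whether CHO RNA was present. Of 26 stromal markers, 23 were below an RPKM of 0.5 in all 4 libraries, 2 were higher in both libraries with CHO cells than in both without, and 19 were lower. The most abundant, FBN1, had an RPKM of 1.89 with DMSO, 1.87 with SM-164, 2.69 on CHO cells and 3.04 on CD30L+ CHO cells.

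**Figure D4:**
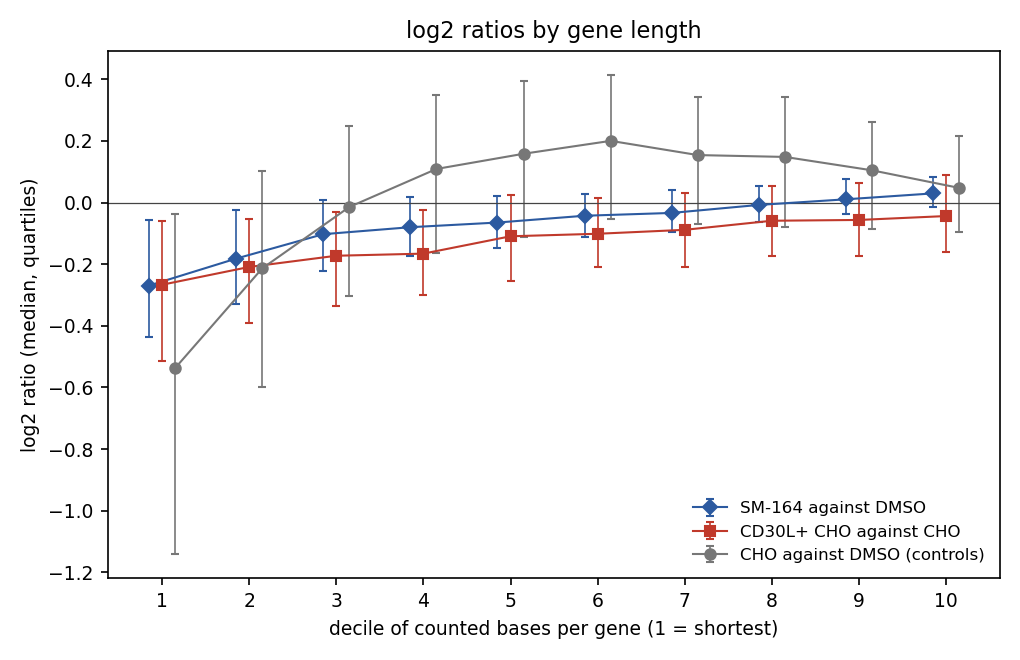
Median log2 ratio by decile of counted bases, from the shortest genes (1) to the longest (10), for the 3 comparisons; bars span the quartiles across genes. The shortest decile lies at -0.27 for SM-164, -0.27 for CD30L and -0.54 for CHO against DMSO.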

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

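The tests on the patterns weighed here were chosen after the results were seen, except the count of lower calls after subtraction of the length trend, which was written down before it was computed. Features counted on the strand opposite to a gene were outside the comparisons, and those at least 2-fold higher than in the control library are given as signal in data not analysed above. Between the controls, without either agent, 58 of 531 antisense features were at least 2-fold higher on CHO cells than with DMSO and 7 at least 2-fold lower. More features thus differed between the experiments than in either comparison below.

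With SM-164, 2 of 409 antisense features were at least 2-fold higher. The antisense feature of BTRC, the gene of an F-box protein that targets IkB for degradation, had 13313 reads against 7011 with DMSO, a log2 ratio of 1.01. It had 3176 reads on CD30L+ CHO cells against 582 on CHO cells, at an RPKM of 0.343 against 0.0624, below the expression minimum, so it was not tested in that comparison. It runs from 103113825 to 103317070 on chromosome 10 (hg19). The sense strand of BTRC had an RPKM of 0.564 against 0.571. The antisense feature of GTF2H2C was at 1.08, from 28 reads against 14 over 400 counted bases.

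On CD30L+ CHO cells, 6 of 598 antisense features were at least 2-fold higher than on CHO cells and 5 at least 2-fold lower. The lower ones include the largest differences, those of LOC728752 (-3.17) and UNC45B (-1.61). The antisense feature of IL21, on chromosome 4 from 123533783 to 123542211, had 431 estimated reads against 96.4, a log2 ratio of 1.46. The antisense feature of PTGER2, a prostaglandin E2 receptor gene, was at 1.22 with 598 reads against 165. The others were those of BEST1 (1.20), AP1AR (1.08), RPS3A (1.03) and MAP3K5 (1.00). The ferritin gene FTH1 overlaps the end of BEST1 on the opposite strand. The counted antisense feature of BEST1 ends at 61731756, just before FTH1 begins, so it leaves this overlap out. TIFA lies next to AP1AR on the opposite strand.

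TNFSF8, the CD30L gene itself, had 100 reads on CD30L+ CHO cells, 1 on CHO cells, 0 with SM-164 and 1 with DMSO. Hamster RNA common to both CHO lines would give like rates in both co-cultures, but the lower counting limit of the fold between them was 17.7, which argues against it. Transcripts of the CD30L construct, carried over with CHO cells, and transcription of the lymphoma cells' own TNFSF8 after CD30 engagement cannot be told apart: the 100 reads are not split into exons and introns.

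BIRC2 was 2.63-fold higher on CD30L+ CHO cells and lies 7830 bp downstream of BIRC3 on the same strand, so transcription running on from BIRC3 is a candidate explanation. If a constant share of BIRC3 transcription ran on, the RPKM gained by BIRC2 per RPKM gained by BIRC3 should be alike in both comparisons. It was 1.51% with SM-164 (simulated counting interval 1.05 to 1.97) and 11.6% with CD30L, with a lower limit of 11.2, which argues against a constant share. With the CD30L share, SM-164 would have added 4.01 RPKM to BIRC2, and it added 0.519. A share that differs between treatments, and a response of BIRC2 itself to CD30, stay open and were not tested, and the experiments also differ in culture.

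The 56 genes lower on CD30L+ CHO cells were mostly short, with a median of 1728 counted bases against 27212 for all tested genes. Not all were: FYCO1 (77913 counted bases), CARS2 (64724) and HTRA3 (37350) had log2 ratios of -1.15, -1.05 and -1.24. In their length deciles the median of all genes lay between -0.09 and -0.06, so the length trend is small there. MYC, with 5366 counted bases, lay outside the shortest decile. Subtraction of the smooth trend with gene length left 24 of the 56 at 2-fold, and the other calls ended because subtraction moved their ratios toward 0. The median log2 ratio of these genes was -1.21 before and -0.96 after subtraction, with quartiles of -1.11 and -0.84. The genes were chosen as 2-fold lower on these same ratios, and the shortest decile of all genes had a median of only -0.27. A remainder well below 0 was therefore fixed in advance, and it cannot decide whether the trend is the whole cause. The same genes were also lower in CHO than in DMSO, where no CD30L was present: 51 of the 56 were below 0 and their median was -1.41, below all 10000 lists matched on gene length, whose medians centred on -0.28. A property of these genes that varies between libraries, such as RNA recovery or GC content, or their response to culture conditions may therefore account for part of the lower calls, and an effect of CD30L itself remains open and untested.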

How the results depend on the processing

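The length trend and length-matched lists were chosen after seeing the data; the other alternatives were not. No paired analysis was possible because each condition has 1 library. In the SM-164 and CD30L comparisons, the signs that changed were those of the gene list medians named with the lists and of the ratio of TNFSF8 with SM-164, which rests on 1 read. List medians between the controls were set beside length-matched lists but not run under the other alternatives. Named genes between the controls, and antisense features, were run under none. Values below stand in the order higher and lower with SM-164 (main 15 and 5), higher and lower with CD30L (75 and 56), higher and lower in both (14 and 1), and different between controls (436).

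The threshold mattered most, by construction: at 1.5-fold the counts were 62 and 87, 201 and 382, 49 and 29, and 1438. A pseudocount of 1, which shrinks low genes, gave 8 and 3, 43 and 15, 8 and 0, and 227; with 0.1, lower genes numbered 9 with SM-164 and 97 with CD30L. Without an expression minimum, 9 were lower with SM-164 and 2 in both; with a mean RPKM of at least 1, 31 were lower with CD30L and 0 in both. TMM scaling gave 113 higher and 32 lower with CD30L and 0 lower in both. With the median set to 0, 0 were lower in both. With at least 1000 counted bases, 1 was lower with SM-164 and 0 in both. With the length trend removed, 0 were lower with SM-164, 24 with CD30L and 0 in both. The correlation of 0.57 was 0.49 without a minimum, 0.62 with a mean RPKM of at least 1 and 0.52 with the length trend removed. The other counts of this series stayed within 1.5 times. The split of the 436 between controls, 71 higher and 365 lower, moved further: higher genes numbered 111 with a pseudocount of 0.1, 104 without a minimum, 46 with a mean RPKM of at least 1 and 133 with the length trend removed, where lower genes numbered 233. At 2-fold, every call had a counting interval that excludes 1; except where a construction is named, the cause was not tested.

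The 15 higher genes with SM-164 were called again under TMM scaling, a median of 0, the 0.1 pseudocount and both expression settings; 14 of them were called with the length trend removed and 8 with a pseudocount of 1. All 75 higher with CD30L were called under these settings too, except 71 with a mean RPKM of at least 1 and 43 with a pseudocount of 1. Of the 56 lower with CD30L, 32 were called under TMM scaling and 24 with the trend removed. Depth limits low genes most: TNF and IL8 rest on 46.5 and 58 control reads.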

Other observations

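The genes in this part were chosen after their values were seen. HGF, the gene of hepatocyte growth factor on chromosome 7 from 81331444 to 81399452 (hg19), had 61 reads with DMSO, 74 with SM-164, 1846 on CHO cells and 6091 on CD30L+ CHO cells. It was 3.32-fold higher on CD30L+ CHO cells than on CHO cells (95% counting interval 3.16 to 3.50) and 20.5-fold higher on CHO cells than with DMSO (15.9 to 26.9). Between these controls its RPKM was 0.592 against 0.0289, a mean below the expression minimum. IL21, the cytokine gene whose antisense feature was higher on CD30L+ CHO cells, had 96.8 estimated reads on its own strand there and 18 on CHO cells, a 5.43-fold difference (3.26 to 9.55), below the expression minimum. CHRNA1, a subunit gene of the muscle acetylcholine receptor, had 51 reads against 2, also below the expression minimum.

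JUNB, an AP-1 gene of anaplastic large cell lymphoma, had an RPKM of 22.2 with DMSO and 22.3 with SM-164 but 2.45 on CHO cells and 0.974 on CD30L+ CHO cells. It is short, with 1816 counted bases. In the shortest decile, 238 of 809 genes were at least 2-fold lower in CHO than in DMSO, with a lower quartile of -1.14. The log2 ratio of JUNB there was -3.05, and its cause was not tested. BATF3 was lower on CHO cells than with DMSO, at 4.94 against 12.1, and reached 13.3 on CD30L+ CHO cells. HMGCS1, an enzyme gene of cholesterol synthesis, was higher in both co-cultures, at 20.8 and 26.6 against 8.45 with DMSO and 7.72 with SM-164.

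HMSD and SERPINB8, both at least 2-fold higher in both comparisons, are neighbours on the same strand of chromosome 18, with 9617 bp between them. The antisense feature of UNC45B on chromosome 17, from 33474836 to 33516364, held 271575 reads with DMSO and 214962 with SM-164, but 4776 on CHO cells and 1240 on CD30L+ CHO cells. It took 0.875% of the DMSO library and 0.0104% of the CHO library, while the sense strand of UNC45B had 0 and 1 reads. The antisense feature of BTRC also differed between the experiments, with 7011 reads with DMSO and 582 on CHO cells.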
